A study of Homo sapiens with 5 samples.

How the data were processed

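The series holds 5 Affymetrix Human Genome U133 Plus 2.0 arrays of total RNA from IMR32, an established human neuroblastoma cell line, carrying a stably integrated, doxycycline-inducible short hairpin RNA (shRNA) against the homeobox gene MEIS1. Per the labels' protocols, the cells grew in DMEM with 10% fetal calf serum, doxycycline was added to switch on the hairpin, RNA was isolated with Trizol and cleaned on RNeasy columns, and 4 µg of total RNA per sample was amplified and biotin-labelled with the One-Cycle kit. There is 1 array at 0 h, before doxycycline, and 1 array each at 24, 48, 96 and 192 h of doxycycline. Each array is 1 RNA sample, so a difference between any 2 arrays has no replicate check. No array of cells kept without doxycycline to a later time is among the 5. Cells given doxycycline without this hairpin are not among them either.

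The submitters' processing notes name MAS5 and GCOS, without versions. The authors' deposited values were read as log2 of the MAS5 signal: they ran upward from 0, and 2 raised to each value lay within 0.01 of a multiple of 0.1 for 100% of the values. The log step, the floor at a signal of 1 (a log2 value of 0) and the scaling target are not given in the sources used here and were read from the values. On the linear scale the mean after trimming 2% from each end was 100.02 to 100.03 on the 5 arrays, so each array had been scaled as a whole, and no further scaling was applied. Between 5.34% and 8.15% of the 54675 probe sets lay at the floor. Detection calls and probe-level intensities were not analysed here. With 1 array per time point, the number of arrays limits the precision. MAS5 subtracts a mismatch-based background, which makes low signals noisy, and a single scaling factor per array leaves shifts that depend on brightness.

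Signals were returned to the linear scale, an offset of 4.7 was added (the median over arrays of the 25th percentile of all signals) and log2 was taken. All log2 changes below are on this log2(signal + 4.7) scale, which understates changes of dim genes. The 62 control probe sets were left out of the tests. GEO's platform annotation names 1 gene for 41091 probe sets and several for 1801; 11721 probe sets have no gene name here and were not used at gene level. Symbols were looked up by gene identifier in the RefSeq table of assembly GRCh38.p14, which held 41043 of the probe sets named for 1 gene and changed 0 symbols. The data name no genome build, so no coordinates are given. Probe sets with a mean signal of at least 17.9 (the median of all signals) were kept, and the probe set with the highest mean signal stood for each gene. This left 11944 of 19775 genes.

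With 1 array per time point only a trend across the arrays leaves residual degrees of freedom. The main test was a limma fit of log2 signal on the time step (0 h, 24 h, 48 h, 96 h and 192 h as steps 0 to 4), moderated with eBayes and trend=TRUE (3 residual and 9.07 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the 11944 genes and a threshold of 0.05. The fitted change is the slope times 4 steps, given as a log2 value ± its standard error (SE). The residual holds noise and any departure from a straight line, and the p-values measure the scatter of 5 single arrays around the line. The words rose and fell are used of genes past this threshold. In 20 simulated data sets with the means and residual spread of these genes, in which 200 of 11944 genes changed, the fit recovered 15.3% of 1.41-fold, 68.3% of 2-fold, 96.4% of 4-fold and 99.9% of 8-fold changes, and 6.73% of its calls were false. The simulated noise was independent between genes and each change was a straight line. In the real residuals the estimated correlation between genes was 0.69 for G2/M genes and 0.84 for ribosomal proteins. The 6.73% is therefore not an estimate of the false calls in these arrays.

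Before the data were examined, 27 gene lists were written down. They were tested with limma's camera on the trend (preset inter-gene correlation 0.01, Benjamini-Hochberg over the 24 lists with at least 5 tested genes). Camera was also run with the correlation estimated from the residuals, and no list passed then. Each list's median was placed among 10000 random lists matched on mean signal in 20 bins, as a description of these arrays. The order of the arrays was permuted exactly (120 orders; the smallest two-sided p is 0.0167). The lists cover TALE factors, HOX genes, genes reported elsewhere as MEIS1 targets, neighbours of MEIS1 and of MYCN on chromosome 2, adrenergic and mesenchymal neuroblastoma genes, catecholamine handling, neuronal differentiation, axon guidance, the Notch and WNT pathways, G1/S, G2/M, MYC targets, ribosomal proteins, p53 and apoptosis, interferon-stimulated genes, amino-acid and ER stress, immediate early genes, cholesterol synthesis, hypoxia, the respiratory chain, extracellular matrix, and markers of Schwann, blood, endothelial and epithelial cells. Each gene list was also counted with adjustment over the list alone.

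The genes named were set by a rule fixed at the same time: all probe sets of a set of TALE genes that includes MEIS1, MEIS2, MEIS3, PBX2, PBX3, PBX4, PKNOX1 and PKNOX2; the 12 genes with the largest fitted rise and the 12 with the largest fitted fall past the threshold; the 4 members of each list with the largest absolute change; the 3 highest and 3 lowest ratios at each time; and the 5 highest and 5 lowest genes at least 2-fold from 0 h at all 4 times. The text names fewer genes of the last 3 parts than the rule gives, and some items it covers are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Alternatives were another offset, filter, normalization (quantile, cyclic loess, equal medians), summary of probe sets, time scale, variance estimate, set test, and leaving out each array in turn. Added after seeing the data were the level of the poly-A spike-in controls as a covariate, and camera with an estimated correlation when 1 array was left out. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.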

Results

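Gene expression was followed in IMR32 neuroblastoma cells, an established human line, after doxycycline switched on an integrated short hairpin RNA against MEIS1, a homeobox transcription factor of the TALE class. One array was run before induction (0 h) and 1 each after 24, 48, 96 and 192 h of doxycycline, 5 arrays in all. The median MAS5 signal of all probe sets was 17.8 at 0 h, 16.0 at 24 h, 18.6 at 48 h, 19.0 at 96 h and 18.0 at 192 h. The 3' to 5' signal ratio of GAPDH lay between 1.02 and 1.08 and that of ACTB between 1.25 and 1.43, so the arrays were close in this measure of RNA integrity. The 24 poly-A spike-in probe sets, which are added to the RNA before labelling, read lower at 48 h (mean log2 difference from 0 h of -0.46), 96 h (-0.63) and 192 h (-0.25) than at 0 h, and 0.10 higher at 24 h. There were no replicates at any time point.

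The first question was how far the targeted transcript fell. The brighter MEIS1 probe set read 1052 at 0 h and 851.5, 847.2, 857.0 and 786.6 at 24, 48, 96 and 192 h, which is 81.0%, 80.6%, 81.6% and 74.9% of the 0 h signal on the scale with the offset. The other MEIS1 probe set read 597.2 at 0 h and 495.9, 560.4, 490.4 and 443.8 later, or 83.2%, 93.9%, 82.3% and 74.5%. Both MEIS1 probe sets were thus below their 0 h signal at all 4 induced times. In the limma trend the gene's fitted log2 change over the course was -0.33 ± 0.14 (SE), with an unadjusted p of 0.0351 and a Benjamini-Hochberg adjusted p of 0.251, so MEIS1 did not pass the threshold. Without the 0 h array the fitted change of MEIS1 was -0.13. Among the 500 genes nearest to MEIS1 in signal, 13.2% had a fitted change as low and 5.2% a ratio at 192 h as low. The hairpin is described as directed against the MEIS1b isoform, and which isoforms these probe sets detect was not analysed here.

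None of the other tested TALE genes passed the threshold. PKNOX2 had the largest fitted log2 change of them, -0.63 ± 0.24 (SE), with a limma adjusted p of 0.201, and its other 2 tested probe sets gave -0.45 and -0.55. The fitted change was 0.22 for MEIS2, 0.29 and 0.33 for the MEIS3 probe sets, 0.12 for PBX3 and -0.02 for PBX4. The 4 PBX2 probe sets ranged from -0.17 to 0.55 and the 5 PKNOX1 probe sets from -0.32 to -0.01. MEIS2 was at 266.7 at 192 h against 196.1 at 0 h, and without the 192 h array its fitted change was -0.40. The list of 10 tested TALE factors had 0 members past the threshold, also when adjusted over the list alone, a median change of -0.06 and a camera adjusted p of 0.698.

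The second question was which genes followed the time of induction. NRP1, a co-receptor for semaphorins and VEGF, rose: its signal went from 61.1 at 0 h through 131.5, 161.9 and 457.1 to 960.3 at 192 h, a fitted log2 change of 3.80 ± 0.25 (SE; limma adjusted p = 3.79e-05), with a positive fitted change in all 3 probe sets. ADCYAP1, which encodes the neuropeptide PACAP, rose from 33.5 to 316.1 (fitted change 3.16 ± 0.26, adjusted p = 1.24e-04). The stathmin family members STMN4 (3.20 ± 0.43) and STMN2 (2.41 ± 0.44), the long non-coding RNA MIAT (2.53 ± 0.34) and the neurotrophin-3 receptor NTRK3 (2.43 ± 0.33; positive in all 9 probe sets) also rose. MIAT went from 143.8 to 691.5 in its brightest probe set, and 3 of its 4 probe sets had a positive fitted change. Such counts of a gene's probe sets, here and for COL1A1 below, cover only those that passed the signal filter. CHRNA1, a subunit of the muscle acetylcholine receptor, fell from 449.6 at 0 h to 149.7 at 24 h and 41.7 at 192 h (-2.92 ± 0.30, adjusted p = 3.88e-04).

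The remaining 6 of the 12 largest rises were those of CNGB1 (3.80), GDF2 (2.76), SHISA2 (2.49), NSG2 (2.48), LOC100505711 (2.46) and ICA1 (2.34). Signals were low at 0 h for CNGB1 (1.8), GDF2 (4.5), STMN4 (8.2), LOC100505711 (8.6) and STMN2 (10.0), so the size of their change depends on the offset. With an offset 4 times smaller and 4 times larger it was 4.93 and 2.24 for CNGB1, 3.48 and 1.61 for GDF2, 3.59 and 2.31 for STMN4, 2.92 and 1.57 for LOC100505711, and 2.73 and 1.68 for STMN2. Among genes that fell, the type I collagen gene COL1A1 went from 584.4 to 115.1 (fitted log2 change -2.31 ± 0.31, negative in all 4 probe sets), the protease gene ADAMTS9 from 381.5 to 73.3 (-2.19), the chemokine gene CXCL12 from 198.9 to 41.2 (-2.14) and F3, tissue factor, from 849.8 to 204.2 (-1.98). DOCK10 (-2.30), AKNA (-2.29), PRKG2 (-2.28), CORO6 (-1.96), KDELR3 (-1.91), ARHGAP28 (-1.91) and HMCN1 (-1.88) fell as well. Some of these became dim, so their change depends on the offset in the same way: it was -3.04 and -1.24 for AKNA, -2.60 and -1.56 for PRKG2, -2.56 and -1.68 for DOCK10, and -2.18 and -1.24 for HMCN1. With the poly-A spike-in level as a covariate, a setting chosen after seeing the data, CNGB1 (limma adjusted p = 0.0841), GDF2 (0.197), LOC100505711 (0.273), STMN2 (0.107), AKNA (0.084), PRKG2 (0.168) and CORO6 (0.14) did not pass.

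In all, 415 of 11944 genes (3.47%) had an adjusted p under 0.05 in the limma trend, of which 241 rose and 174 fell, and 2028 genes had an unadjusted p under 0.05. The fitted change was at least 2-fold for 142 of the genes that rose and 81 of those that fell. With array medians set equal 187 rose and 225 fell, so 45.4% of the called genes rose against 58.1% here. Of the 415 genes, 76 also passed without each array in turn; of the 69 genes named as past the threshold in the text, 20 did so, namely NRP1, ADCYAP1, STMN4, MIAT, NTRK3, CHRNA1, COL1A1, ADAMTS9, CXCL12, F3, ARHGAP28, PRPH, DDC, CHGB, TBX3, EYA1, VCAN, YAP1, BAMBI and H2BC21, and the other named calls were lost without at least 1 array. The count was 190 without the 0 h array, 254 without the 96 h array and 240 without the 192 h array.

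**Figure D1:**
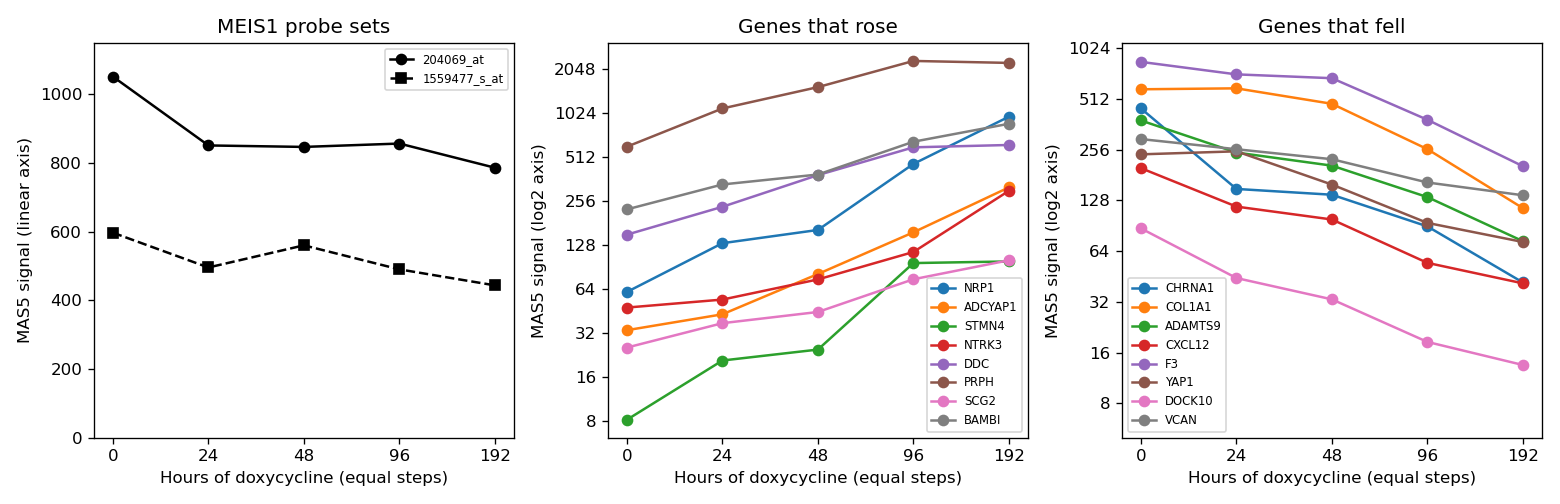
MAS5 signal (log2 axis in the panels of rising and falling genes) against hours of doxycycline in equal steps, 1 array per point. The MEIS1 probe sets stay at 74.5% or more of their 0 h signal on the scale with the offset, while NRP1 rises to 960.3 and CHRNA1 falls to 41.7 at 192 h.

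The gene lists were counted again in 6 reruns, which left out each array in turn or used the spike-in covariate. Of 31 tested genes of neuronal differentiation 12 rose and 0 fell (21 and 0 adjusted over the list alone; 7 to 12 rose in the reruns), with a median fitted log2 change of 0.74. Besides STMN4, NTRK3 and STMN2, the intermediate filament gene PRPH rose from 599.3 to 2236.6 (1.94 ± 0.22, limma adjusted p = 6.2e-04). Camera gave the list an adjusted p of 3.02e-16, and the adjusted p = 0.267 with an estimated correlation. Catecholamine genes had 5 of 15 tested members that rose and 0 that fell (6 and 0 adjusted over the list alone; 4 to 5 rose in the reruns), with a median of 0.29. DDC, which makes dopamine from L-DOPA, rose from 150.4 to 615.6 (2.13 ± 0.20), and the granin genes SCG2 (1.81), CHGB (1.32) and SCG3 (1.25) rose too. Apart from DDC, the members that rose were all granin genes. The fitted change was -0.008 for DBH, -0.02 for GCH1, 0.002 for SLC6A2, 1.04 for PNMT and 0.65 for MAOA. None of these genes, chosen after their values were seen, passed the threshold. For the catecholamine genes camera gave an adjusted p of 9.16e-06, and the adjusted p = 0.267 with an estimated correlation.

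Of 21 tested adrenergic transcription factors, 4 rose and 1 fell (9 and 4 adjusted over the list alone; 3 to 5 rose and 1 fell in the reruns). TBX3 (fitted log2 change 1.72), SIX3 (1.65) and GATA2 (1.62) rose, EYA1 fell from 817 to 383.1 (-1.17 ± 0.15; chosen after its values were seen), and LMO1 had a fitted change of 1.26 with a limma adjusted p of 0.195. The list's camera adjusted p was 0.0207, and the adjusted p = 0.602 with an estimated correlation; it was 0.063 without the 96 h array and 0.191 with the spike-in covariate. Among 22 axon guidance genes 5 rose and 0 fell (7 and 1 adjusted over the list alone; 2 to 4 rose and 0 to 1 fell in the reruns), with a median of 0.40. Their median log2 ratio to 0 h was first negative, -0.19 at 24 h (percentile 0.82 of matched random lists). It was 0.11, 0.21 and 0.30 at 48, 96 and 192 h, so the course was not a steady rise from 0 h. The netrin receptor gene UNC5A (1.96) and SLIT3 (1.28) rose along with NRP1, while NRP2 had a fitted change of -1.03 with an adjusted p of 0.0931. For axon guidance genes the camera adjusted p was 0.0113, the adjusted p = 0.602 with an estimated correlation, and 0.0616 with the spike-in covariate.

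Of 32 tested extracellular matrix genes 0 rose and 4 fell (1 and 10 adjusted over the list alone; 2 to 4 fell in the reruns), with a median fitted log2 change of -0.45. COL1A1 led them, the proteoglycan gene VCAN fell from 295.9 to 137.3 (-1.12 ± 0.17, limma adjusted p = 0.00389) and the fibrillin gene FBN2 fell by 1.07 on the log2 scale, while TNC had a fitted change of -1.39 with an adjusted p of 0.0583. The camera adjusted p of the extracellular matrix genes was 2.4e-05, and the adjusted p = 0.267 with an estimated correlation. Of 18 tested mesenchymal genes 1 rose and 2 fell (1 and 5 adjusted over the list alone; 0 to 2 rose and 2 to 3 fell in the reruns), with a median of -0.12. That median lay at percentile 7.73 of matched random lists, and COL1A1, a member of both lists, was 1 of the 2 genes that fell. The Hippo pathway effector YAP1 fell from 240.2 to 72.5 (-1.88 ± 0.23), SOX9 rose from 130.1 to 413.5 (1.70 ± 0.32), and CCN1 had a fitted change of -0.76 with an adjusted p of 0.132. The camera adjusted p of the mesenchymal genes was 0.046, the adjusted p = 0.602 with an estimated correlation, and 0.653 without the 192 h array.

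Cell cycle lists had negative fitted changes of small size. The median log2 ratio to 0 h of G2/M genes was -0.24, -0.20, -0.51 and -0.31 at 24, 48, 96 and 192 h. For G1/S genes it was -0.05, -0.09, -0.30 and -0.25, so neither list fell at every step. Of 32 G1/S genes 0 rose and 1 fell, also when adjusted over the list alone, with a median fitted log2 change of -0.30 (camera adjusted p = 8.89e-08; adjusted p = 0.461 with an estimated correlation). GINS1, part of the replicative helicase, fell from 1772.7 to 1177.5 (-0.59 ± 0.13), and CDT1 (-0.56), TYMS (-0.46) and MCM3 (-0.44) did not pass. In the reruns 0 to 1 of the G1/S genes fell, with 0 without the 0, 24 or 96 h array. Of 35 G2/M genes 0 rose and 2 fell (0 and 6 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 1.26e-09; adjusted p = 0.605 with an estimated correlation). These were the mitotic genes KIF23 (-0.69, limma adjusted p = 0.0417) and BUB1 (-0.59, 0.0498), while PLK1 had -0.57 and HMMR -0.56 without passing. The number of G2/M genes that fell was 0 without the 0, 48 or 96 h array and with the spike-in covariate, 1 without the 24 h array and 4 without the 192 h array.

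Of 15 interferon-stimulated genes 0 rose and 4 fell (0 and 5 adjusted over the list alone), with a median fitted log2 change of -0.15. That median lay at percentile 5.78 of matched random lists. In the reruns 0 to 5 fell, with 0 without the 192 h array and 2 without the 0 h array. IFI44L went from 613.9 to 116.2 (-1.83 ± 0.42), IFI44 from 1092.4 to 302.9 (-1.56), IFITM2 from 358.3 to 143.0 (-1.20) and IFITM3 from 769.6 to 337.5 (-1.07). By camera the adjusted p of the interferon-stimulated genes was 0.046, the adjusted p = 0.685 with an estimated correlation, and 0.489 without the 192 h array. None of 15 tested cholesterol synthesis genes passed, also when adjusted over the list alone, though the list's median was -0.27 (camera adjusted p = 0.0207; adjusted p = 0.793 with an estimated correlation; 0.741 without the 192 h array for cholesterol synthesis). SQLE had a fitted change of -0.53 and INSIG1 -0.56.

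The other lists did not pass camera's threshold. Of 14 tested WNT pathway genes 2 rose and 1 fell (3 and 2 adjusted over the list alone; median fitted log2 change 0.07; camera adjusted p = 0.565): BAMBI, a decoy receptor of the TGF-beta family, rose from 223.7 to 859.3 (1.92 ± 0.15), SFRP1 rose by 1.03 and APCDD1 fell by 1.77 on the log2 scale. Of 20 Notch pathway genes HES6 fell (-0.90), DLL1 had -0.85 with a limma adjusted p of 0.0696, and the list had a median of -0.06 (0 and 2 adjusted over the list alone; adjusted p = 0.565). Of 24 p53 targets and apoptosis genes ZMAT3 rose (0.97), TP53INP1 had 1.09 with an adjusted p of 0.0703, and the list had a median of 0.16 (2 and 0 adjusted over the list alone; adjusted p = 0.0666, and 0.0405 without the 24 h array, where it was 0.665 with an estimated correlation). DUSP1 rose (0.86) among 15 immediate early genes (2 and 0 adjusted over the list alone; adjusted p = 0.565), where the median was -0.06 but the mean was 0.17 and camera's direction up, with JUN at 1.36 (adjusted p = 0.0552). In the reruns 1 to 2 WNT pathway genes rose and 0 to 1 fell, 0 to 1 Notch pathway genes fell, and 0 to 2 of the p53 and 0 to 2 of the immediate early genes rose.

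Of 42 tested respiratory chain genes NDUFC1 fell (-0.82; 0 and 2 adjusted over the list alone; 0 to 2 fell in the reruns; list median -0.02, camera adjusted p = 0.479). Of 24 hypoxia genes 0 passed (1 and 0 adjusted over the list alone; 0 to 1 rose in the reruns); the list's median was -0.04, its mean 0.10 and its camera direction up (adjusted p = 0.753), with NDRG1 at 1.26 and ADM at 1.19. The 11 tested HOX genes had 0 members past the threshold (0 and 1 adjusted over the list alone; 0 to 1 fell in the reruns) and a median of -0.07 (adjusted p = 0.565), with HOXD1 at -0.95 and HOXD13 at -0.92. No member passed, over all genes or adjusted over the list alone, among 10 reported MEIS1 targets (median 0.04, mean -0.02, camera direction down, adjusted p = 0.78), 12 neighbours of MEIS1 on chromosome 2 (median -0.05, adjusted p = 0.78), 10 neighbours of MYCN (-0.09, 0.565), 25 MYC and ribosome biogenesis genes (-0.02, 0.565), 35 ribosomal proteins (-0.02, 0.78) or 27 stress response genes (median 0.02, camera direction down, adjusted p = 0.886). At the preset correlation, camera passed some of these when 1 array was left out, with few members past the threshold. Without the 0 h array stress response genes had a mean of 0.33 (adjusted p = 0.0196; 0.495 with an estimated correlation) and 0 of 27 members past it. Without the 192 h array ribosomal proteins had 0.34 (1.51e-12; 0.579 with an estimated correlation; 1 of 35 rose) and respiratory chain genes 0.10 (0.0464; 0.715; 0 of 42 rose and 1 fell). Signals of markers of other cell types were low. Of the Schwann cell list only ERBB3 was tested (fitted log2 change 1.03, limma adjusted p = 0.316), of the blood and endothelial list only CDH5 (-0.43, 0.752), and of the epithelial list ESRP1 (-1.60, 0.173), KRT7 (0.52, 0.538) and KRT8 (0.41, 0.712), and none of these 5 genes passed.

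**Figure D2:**
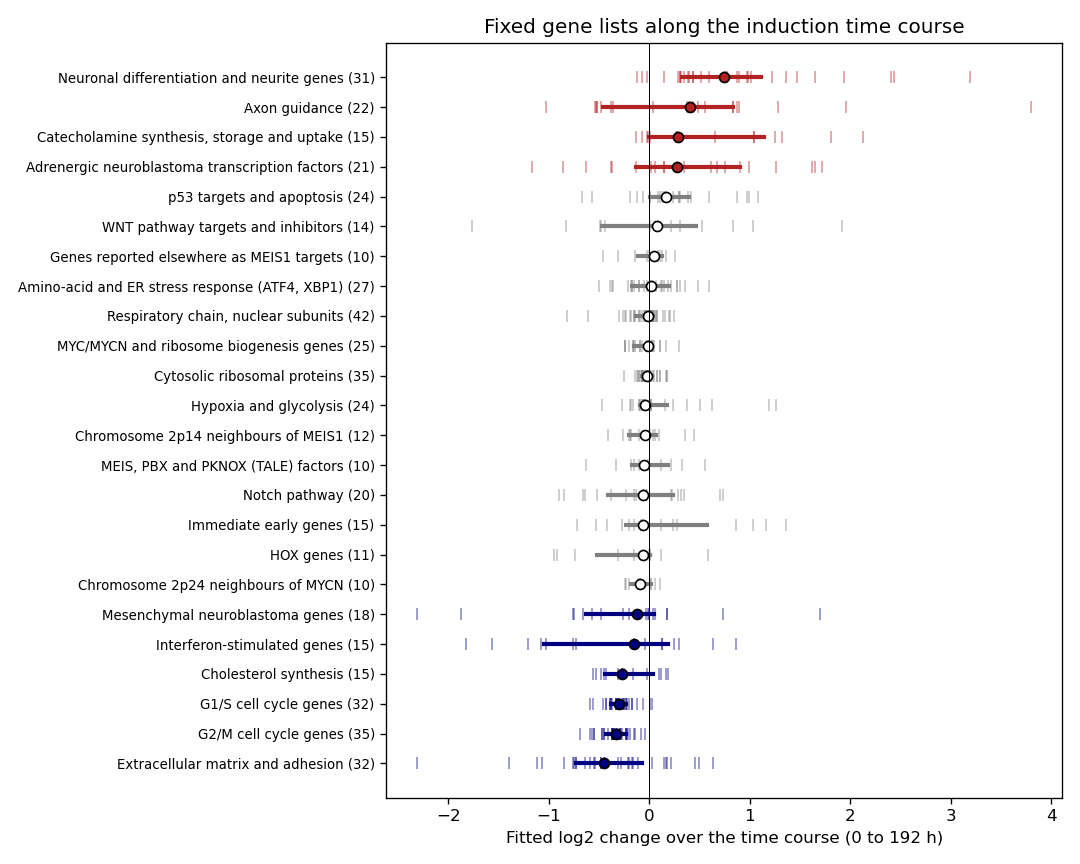
Fitted log2 change over the course for the 24 lists with at least 5 tested genes. Ticks are genes, circles medians and bars the middle 50% of the members, red and blue mark lists that passed camera upward and downward at the preset correlation, and numbers in brackets count tested genes. Neuronal genes have the highest median, 0.74, and extracellular matrix genes the lowest, -0.45.

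A further comparison set each induced array against the 0 h array without a test. At 24 h the highest ratios on the scale with the offset were those of the immediate early gene EGR1 (28.7 at 0 h and 145.4 at 24 h, 4.49-fold), TRIM67 (4.33-fold, from 1.4 to 21.7) and SSTR5-AS1 (10.2 to 58.0, 4.21-fold). EGR1 read 174.2 at 48 h, 81.9 at 96 h and 116.0 at 192 h, and its fitted log2 change of 1.17 had a limma adjusted p of 0.399 and was -0.80 without the 0 h array. At 96 h CNGB1 (10.6-fold) and STMN4 (7.82-fold) were among the 3 highest, and at 192 h NRP1 (14.7-fold) was the highest. TRIM67, CNGB1 (1.8 at 0 h), STMN4 (8.2) and SSTR5-AS1 were dim before induction, so the size and rank of their ratios depend on the offset. With an offset 4 times smaller and 4 times larger the fitted log2 change was 3.20 and 1.22 for TRIM67, 4.93 and 2.24 for CNGB1, 3.59 and 2.31 for STMN4, and 2.48 and 1.58 for SSTR5-AS1. The lowest ratios at 192 h were those of CHRNA1 (0.102), IFI44L (0.195) and DOCK10 (0.198).

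The number of genes 2-fold higher or lower than 0 h at 24 h was 194 (81 higher, 113 lower), and genes 2-fold higher or lower than 0 h at 48 h numbered 207 (129 and 78). There were 402 genes 2-fold higher or lower than 0 h at 96 h (262 and 140) and 504 at 192 h (273 and 231). Between neighbouring induced arrays the totals were 187 for 24 and 48 h, 222 for 48 and 96 h, and 215 for 96 and 192 h. These totals depend on the offset and the filter: with 4 times the offset, without a filter and with a stricter filter, genes 2-fold higher or lower than 0 h at 24 h numbered 41, 1410 and 24, and genes 2-fold higher or lower than 0 h at 192 h 255, 1827 and 231. The share that was higher depended on the scaling. At 24 h it was 41.8%, against 53.6% after quantile normalization, 54.6% after cyclic loess and 58.2% with equal medians. With equal medians it was 51.5% at 48 h against 62.3%, and 54.1% at 96 h against 65.2%.

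At all 4 induced times 37 genes were at least 2-fold higher than at 0 h and 2 at least 2-fold lower. The number of genes 2-fold away from 0 h at all 4 induced time points, 39 here, was 55 with an offset 4 times smaller, 6 with 4 times the offset, 149 without a filter and 11 with a stricter filter. The genes highest at all times included SSTR5-AS1, NRP1, TRIM67 and SDK2, a cell adhesion gene that read 15.6 at 0 h and 67.3, 76.6, 94.4 and 101.2 later. The lower genes were CHRNA1 and STC1, which encodes a secreted glycoprotein and read 252.1 at 0 h and between 88.7 and 121.8 afterwards. Taking another array as the one set apart gave 32 genes for 24 h, 13 for 48 h, 22 for 96 h and 55 for 192 h, against 39 for 0 h. The 4 ratios share the 0 h array, so what they have in common can stem from that array.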

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

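Of the tests below, those of the order of the arrays, of the amino-acid stress response and of the spike-in covariate were chosen only after the results they bear on had been seen. The other explanations were given their bounds before the test, but for patterns already seen in these arrays.

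Signal in probe sets outside the main comparisons drew attention in 28 cases. Among 4318 probe sets named for several genes or for none, 28 followed the time step (18 rose, 10 fell). The steepest fall was that of a probe set annotated to PIR-FIGF and VEGFD, from 638.1 at 0 h to 93.9 at 192 h (fitted log2 change -2.63, limma adjusted p = 6.9e-04). A probe set without a gene name here went from 5.7 to 62.5.

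The control probe sets stood out too. At 96 h the hybridization spike-ins read 0.251 higher on the log2 scale than at 0 h and the poly-A spike-ins -0.63, and the hybridization spike-ins of 192 h were at -0.18.

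The first pattern weighed was that 415 genes followed the time step. For chance order of the arrays, 1 of 60 orders gave as many genes by the adjusted count, the real one, and the highest other order gave 233. That other order had 2098 genes at an unadjusted p under 0.05 against 2028 for the real one. It had 526 genes moving in 1 direction throughout against 538. A share of 1 in 60 is the smallest this test can give, and the test was chosen after the result was seen. The real order thus ranked first by the adjusted count, but chance order was not excluded. A batch of labelling seen in the poly-A spike-ins was examined in disjoint pairs of arrays. Spike levels were close for 0 and 24 h (mean log2 8.196 and 8.299) and for 48 and 96 h (7.736 and 7.565). They were less close in other pairs, such as 24 and 192 h (8.299 and 7.942), where the 0.58 below was measured. The 200 genes that rose most from 48 to 96 h and the 200 that fell most differed by 0.171 in log2(24 h / 0 h). This was above the upper bound set from random lists (0.0957). The rising genes had a median of -0.0319, with 96 of 200 above 0, and the falling genes -0.203, so the rising genes did not rise again. Of the other 8 comparisons of pairs, 3 lay above their bounds (0.164, 0.175 and 0.58) and 3 within (0.0117, 0.0265 and -0.0246). The 0.164 is the first comparison with its pairs exchanged. The other 2, selected from 96 to 192 h, were opposite (-0.166 at percentile 0.03 and -0.137 at percentile 0.66 of random lists). The batch was therefore not decided. With the spike-in level as a covariate 230 genes were called, 182 of them among the 415. An amino-acid stress response to doxycycline was not decided by the stress response genes. They reached at most percentile 8.55 of matched random lists against 0 h, but the percentiles of all induced times share the 0 h array. Without that array the list's mean fitted change was 0.332, with 0 of 27 members past the threshold. Time in culture cannot be told apart from the knockdown, since 0 uninduced arrays of later times were at hand. Nor can doxycycline itself, since no array of doxycycline-treated cells without this hairpin was at hand.

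The second pattern was that ribosomal protein signals lay above 0 h at 48 h (median log2 ratio 0.218) and 96 h (0.225) and below it at 192 h (-0.145). The non-ribosomal genes nearest in signal had medians of 0.154 at 48 h, 0.147 at 96 h and -0.181 at 192 h. The hybridization spike-ins, which are not from the cells, were at 0.183, 0.251 and -0.183 at these times. After quantile normalization the ribosomal median was 0.0094, -0.0064 and 0.0361. After cyclic loess the ribosomal median at 96 h was 0.178, against 0.093 for the neighbours. A scale shift of bright probe sets may account for part of the pattern, what remains was left open, and no biological explanation was tested.

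The third pattern was that MEIS1 mRNA still lay at 74.9% of its 0 h signal at 192 h. Of 1063 genes as bright as MEIS1 or brighter at 0 h, 43 were under 75% of their 0 h signal at 192 h. Of these, 19 passed the threshold, so bright probe sets could read that much lower. Saturation would make a fall smaller without hiding it, so these counts cannot decide whether it reduced the change of MEIS1. A weak knockdown, an isoform the probe sets do not separate and mixed induction among cells stay open as untested.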

How the results depend on the processing

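The spike-in covariate, and the estimated correlation with 1 array left out, were chosen after seeing the data. No paired analysis was possible because each time point has 1 array. With 1 array per time the precision is limited by the number of arrays, and signals near the floor carry little above background. The fitted change of MEIS1 stayed negative and short of the threshold under all alternatives run, from -0.13 to -0.40 when 1 array was left out. For genes changed with induction time the count was 21 without a filter (more genes tested, dim ones included), 0 by ordinary least squares without moderation (1497 at an unadjusted p under 0.05), 230 with the spike-in covariate, and from 190 to 416 when 1 array was left out. All 415 kept their direction, except that under the stricter filter 380 of them were tested, all with the same direction. In gene lists over time, 10 passed, 0 passed with the correlation estimated (also when 1 array was left out), by fry or by the exact order permutation, and 6 without a filter or with the mean of all probe sets. The exact order permutation cannot go below p = 0.0167, and its lowest adjusted p here was 0.2. Among genes 2-fold higher or lower than 0 h at 24 h the total was 41 with 4 times the offset, 1410 without a filter and 24 with a stricter one; for genes 2-fold higher or lower than 0 h at 48 h, 50, 1721 and 39; for genes 2-fold higher or lower than 0 h at 96 h, 175, 1857 and 155; for genes 2-fold higher or lower than 0 h at 192 h, 255, 1827 and 231; and for genes 2-fold away from 0 h at all 4 induced time points, 6, 149 and 11. These follow from the offset and from the number of dim genes tested. The cause of the turns below was not tested. Without a filter, reported MEIS1 targets turned to 0.0152, WNT pathway to -0.0725 and stress response genes to -0.0473. Stress response genes turned to -0.00976 with the stricter filter, -0.0705 with equal medians and -0.0136 with the square root of the hours. WNT pathway was -0.0171 with equal medians and ribosomal proteins 0.0141 after quantile and 0.0598 after loess normalization. The reported MEIS1 targets were 0.0351 with the mean of probe sets and 0.0163 with hours, where MEIS1 neighbours were 0.00604. With the spike-in covariate the values were 0.0347 for reported MEIS1 targets, 0.0444 for MEIS1 neighbours, -0.043 for WNT pathway, -0.00734 for PBX3, 0.0804 for CDT1 and -0.0666 for KRT8. When 1 array was left out, the ranges that crossed 0 were -0.161 to 0.0283 for MEIS1 neighbours, -1.14 to 0.429 for CDH5, -0.796 to 1.75 for EGR1, -0.334 to 0.0258 for HOX genes, -0.185 to 1.18 for ID1, -0.398 to 0.393 for MEIS2, -0.142 to 0.0295 for Notch pathway, -0.111 to 0.125 for PBX4, -1.40 to 0.565 for STC1, -0.0473 to 0.0194 for TALE factors, -0.112 to 0.082 for reported MEIS1 targets, -0.12 to 0.0971 for respiratory chain, -0.158 to 0.345 for ribosomal proteins and -0.148 to 0.332 for stress response genes. Of 1229 values of the 69 named genes past the threshold, 902 stayed past it, 327 did not and 0 turned. Of 616 values of 35 named genes not past it, 30 passed and 9 turned. The 69 genes and the 415 were selected by their slope in these same arrays, and another variance estimate leaves that slope unchanged. Their kept direction was thus partly fixed in advance.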

Other observations

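The gene groups in this part were picked after the values had been seen, and the lists for BMP, Hippo and histone genes were written then, so their tests describe these arrays and are not independent evidence.

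Targets and inhibitors of BMP signalling rose in part. Of 17 tested members 6 rose and 0 fell: BAMBI (fitted log2 change 1.92), ID3 (1.52), ID4 (1.05), ID2 (0.86), SMAD9 (0.84) and ATOH8 (0.71). ID3 read 88.0 at 0 h and 283.7 at 24 h, and ID1 841.4 and 1964.6, with a fitted change of 0.73 and a limma adjusted p of 0.252 for ID1. Among 21 genes of the Hippo pathway and YAP1 targets 0 rose and 6 fell: YAP1 (-1.88), the kinase gene LATS2 (-1.61), PTPN14 (-1.32), AJUBA (-1.27), the kinase gene STK3 (-0.89) and MOB1A (-0.53). Of 17 histone cluster genes 5 rose and 0 fell, H2BC21 (1.73), H2AC25 (1.59), H2AC6 (1.48), H2BC5 (1.34) and H2BC12 (0.98), though close copies within this family can share probes. The camera adjusted p was 9.51e-06 for BMP, 4.09e-08 for Hippo and 1.15e-04 for histones, and 0.0773, 0.0607 and 0.0773 with an estimated correlation. Without the 0 h array BAMBI, YAP1, AJUBA, STK3, H2BC21 and H2AC25 still passed and the other named members did not, and without each array in turn only BAMBI, YAP1 and H2BC21 passed.

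A hypothesis is that a BMP response may underlie the rise of the ID genes, BAMBI, SMAD9 and ATOH8. The other 11 tested members of the list had a median fitted log2 change of 0.269, at percentile 96.6 of matched random lists, and 6 of them were higher. This was short of the bound set for a shared response, and leaving out the called members lowers the median, so nothing was decided.

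The called genes were selected for a straight trend over time, so the shape of their course is no separate finding. The median log2 ratio to 0 h of the 241 genes that rose was 0.25 at 24 h, 0.43 at 48 h, 0.90 at 96 h and 1.08 at 192 h, with the largest step between 48 and 96 h in 125 of them. The 174 genes that fell had -0.18, -0.37, -0.69 and -0.99.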
